A study of Homo sapiens with 6 samples.

How the data were processed

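RNA of 6 LX2 libraries was measured, 3 given GDF15 at 1 ug/ml for 24 h and 3 untreated. Per the labels' protocols, ERCC spike-in RNA was added to total RNA, poly(A) RNA was selected on oligo(dT) beads, and libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 with genome build GRCh38. The notes give no order or settings, and the gene annotation and the use of strand in counting are not given in the sources used here. Without stated strand, reads of a gene and of an overlapping or antisense gene cannot be told apart.

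The authors deposited 1 table with a row per feature. Its log2 values are the authors' log2 fold change of GDF15 over untreated, a sign checked against the group means, and its p-value columns hold the authors' unadjusted and adjusted p. The 6 columns of deposited signal per library hold values normalized by the authors, called normalized counts here. In each of these columns 100% of the values were whole multiples of a single step, within 0.001 of a step, with steps from 0.792 to 1.12 and a ratio of largest to smallest of 1.42. This is what division by a single factor per library gives, and such a factor corrects neither GC content nor transcript length. Every row had an unadjusted p under 0.05, so the table is selected on the outcome, and features without that p were not analysed here. Full library depth is unknown for that reason, and no counting interval was given.

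Column names matched sample titles for all 6 libraries, and 0 columns per sample were left unmapped. Means and SDs were computed over 3 libraries per group, and folds are ratios of these means. Log2 ratios of means differed from the deposited log2 fold changes by at most 0.031. Of the features, 451 had identifiers with coordinates in GENCODE release 29 on GRCh38, used for positions, GC content and transcript length. A current symbol was found for 449. The table had 2 rows without a gene name and 1 name that reads as a date, and these are not named in the text.

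The design was fixed before the data were examined. It had a count test for raw counts and limma for normalized values of all genes. Neither could give adjusted p-values here, because the values of unlisted genes are needed for them, so the count of genes passing an adjusted p of 0.05 is that of the authors. Limma 3.58.1 in R 4.3.3 was run on log2(normalized count + 1) within the listed features, and its fold changes on this scale understate those of low genes. The smallest p of an exact permutation test of 3 against 3 libraries is 0.10, so single genes were not tested that way. In data simulated for 453 features with 200 changed, limma at an unadjusted p under 0.05 recovered 37.5% of features changed 1.5-fold, 86.5% of those changed 2-fold and 100% of those changed 4-fold. Of unchanged features it called 6.72%, 4.74% and 6.72% in these settings. Every simulated feature had the same dispersion, 0.0596, the median over the listed features, and no simulated library stood apart. Recovery in the measured libraries, where single libraries held many extreme values, may be lower.

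Gene lists, 28 in all, were fixed before the data were examined, and 14 had a listed member. For each of the 14, higher and lower members were compared with the other listed features by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 14. Of random lists of 11 drawn from the listed features, 5.67% had p under 0.05, which is no check for lists whose genes vary together. The direction test asks whether the listed members lean one way more than the other listed features do, and genes are not independent replicates. A count "adjusted over the list alone" uses the deposited p of listed members and counts unlisted members as tested with a p of 0.05 or more. Camera was run within the listed features for lists with at least 2 listed members.

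The rule for genes named in the text took the 15 largest log2 fold changes each way among genes with an adjusted p under 0.05, a mean of at least 20 normalized counts and no overlap between the groups' libraries. It added the 3 members of each list with the smallest adjusted p under 0.05, and GDF15, GFRAL and RET. As no gene had such an adjusted p, the rule named 0 genes beyond the last 3. It was then applied with unadjusted p, a choice made after seeing the data, which named 58 genes with GDF15. Other list members given with a value were chosen after their values were seen. A Y-linked gene among those named is not reported here.

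Alternatives tried were pseudocounts of 0.1 and 5, a minimum mean of 10, a mean of at least 100, fold minimums of 1.5 and 2, an adjusted p under 0.01, other list tests, a replicate block, and leaving out each library in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.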

Results

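LX2 is an established human hepatic stellate cell line, a laboratory model of the liver cells that store retinoids at rest and deposit matrix when activated. The cell type label of the samples reads epithelial, whereas the design text speaks of hepatic stellate cells, which is followed here. GDF15 is a secreted stress-induced cytokine of the TGF-beta superfamily whose known receptor is GFRAL with RET as co-receptor. The study asked how GDF15 acts on stellate cells in connection with liver metastases of uveal melanoma. Poly(A) RNA was sequenced from 3 libraries of LX2 cells given recombinant GDF15 protein at 1 ug/ml for 24 h and from 3 libraries of untreated cells. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

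The values analysed here cover 453 features, 452 genes and 1 ERCC spike-in RNA, each with an unadjusted p under 0.05 in the authors' deposited table. Normalized counts of the listed features summed to 470046, 326126 and 322718 in GDF15 replicates 1, 2 and 3. They summed to 317726, 304048 and 279332 in untreated replicates 1, 2 and 3. These sums cover a selected part of each library, so the full depth of the libraries is unknown. Means below are of normalized counts, given ± SD with n = 3 libraries per group.

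The genes listed as higher with GDF15 included 8 of 41 NF-kB, cytokine and chemokine genes such as TNFAIP2, 9 of 44 interferon-stimulated genes such as XAF1, 11 of 31 hypoxia and glycolysis genes such as SLC16A3, and the collagen gene COL27A1. The genes listed as lower included 4 metallothioneins and the cystine transporter gene SLC7A11. No gene passed an adjusted p of 0.05, and unlisted members of these lists were not analysed here. No gene list passed an adjusted p of 0.05 in the direction test (lowest adjusted p 0.0592, Fisher's exact test). Without GDF15 replicate 1 the median log2 ratio of means went from 1.30 to 0.41 for listed NF-kB, cytokine and chemokine genes and from 0.83 to 0.23 for listed interferon-stimulated genes. Without untreated replicate 2 that of the listed oxidative stress and metallothionein genes went from -2.20 to -0.84. In all, 274 features were higher and 179 lower in the authors' deposited table, with median log2 fold changes of 0.70 and -0.59. The fold changes of that authors' deposited table ran from -3.30 for MT1X to 4.52 for CSF3. A change of at least 2-fold was listed for 63 higher and 17 lower features. The libraries of both groups did not overlap for 307 features, 169 higher and 138 lower, where chance alone gives 10% of features without selection.

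No listed gene passed the test for many genes. The adjusted p was 0.911 for every feature in the authors' deposited table, so 0 genes were higher and 0 lower at an adjusted p under 0.05, against 274 and 179 at an unadjusted p under 0.05. If that adjustment was Benjamini-Hochberg, it covered at least 11024 features, of which chance alone would put 551 under an unadjusted p of 0.05. Within the listed features, limma on log2(normalized count + 1) gave an unadjusted p under 0.05 for 104 higher and 55 lower features. The higher count was 55 without untreated replicate 2 and 57 without untreated replicate 3, and the lower count was 26 without GDF15 replicate 2 and 24 without GDF15 replicate 3. Of 57 named genes other than GDF15, 36 had such a limma p with all libraries. XAF1, CLDN1, VCAM1, IRF1, PARP9, TAPBP, FLT1, PFKFB3, PFKFB4, PLAU and ENG were among those without it. Because the features were listed for their difference, these limma counts describe the list and are no separate evidence of an effect.

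A single library of each group held the extreme value for many features. GDF15 replicate 1 held the highest value of 180 of the 274 higher features, and untreated replicate 2 the highest value of 154 of the 179 lower features and the lowest of 185 higher features. Without untreated replicate 2 the median log2 ratio of means of the lower features went from -0.59 to -0.34, and without GDF15 replicate 1 that of the higher features went from 0.70 to 0.48. With both libraries left out, an alternative chosen after seeing the data, the medians were 0.35 and -0.30, and 270 of 274 higher and 179 of 179 lower features had their listed direction. The features were listed for a difference that includes the remaining libraries, and the 307 without overlap cannot turn. Kept directions are therefore no separate evidence.

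The GDF15 transcript of the cells, which is not supplied by the added protein, was among the listed features, and its receptor genes were not. GDF15 (ENSG00000130513, GRCh38 chromosome 19, 18374731 to 18389176, plus strand) had 54.5 ± 37.8 normalized counts with GDF15 and 25.9 ± 1.88 without (SD, n = 3), a 2.11-fold difference. The groups overlapped, with 94.1, 50.6 and 18.8 normalized counts in GDF15 replicates 1, 2 and 3 and 27.0, 23.7 and 26.9 in the untreated libraries. Its unadjusted p was 0.0340 in the authors' deposited table and 0.178 by limma on the log scale. Its log2 ratio of means was 1.08 with all libraries and 0.42 without GDF15 replicate 1. Of the 12 genes in the list of GDF15, its receptors and proposed partners, the other 11, GFRAL and RET included, were not among the listed features.

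Inflammatory genes were listed as higher, among them CSF3 with the highest fold change of the list. All 8 listed members of the 41 NF-kB, cytokine and chemokine genes were higher, among them the monocyte chemoattractant CCL7, the TNF-induced gene TNFAIP2 and the leukocyte adhesion molecule VCAM1. TNFAIP2 (ENSG00000185215, chromosome 14, 103123442 to 103137439) had 5837 ± 3859 normalized counts with GDF15 and 2496 ± 544 without (SD, n = 3), a 2.34-fold difference. By limma on the log scale its unadjusted p was 0.0447 with all libraries and 0.0677 without GDF15 replicate 1. TNFAIP2 also lost a limma p under 0.05 without untreated replicate 1, untreated replicate 2 or untreated replicate 3. CCL7 had 24.95 ± 26.8 and 4.33 ± 1.27, and VCAM1 88.0 ± 90.6 and 29.3 ± 4.51. The NF-kB inhibitor gene NFKBIA and the subunit gene NFKB2 were 1.85-fold and 1.49-fold higher, with overlapping groups. Groups did not overlap for only 2 of the 8 members. CSF3, the gene of granulocyte colony-stimulating factor, was near the floor outside GDF15 replicate 1, which held 142 normalized counts against 7.9 and 2.2 in the other GDF15 libraries and 0 to 5.5 in untreated cells. All 8 members were highest in GDF15 replicate 1, and the median log2 ratio of means of the list was 1.30 with all libraries and 0.41 without that library. Fisher's exact test of direction against the other listed features gave p = 0.0246 and adjusted p = 0.0861 over 14 lists, two-sided. Of the members, 2 had an adjusted p under 0.05 when adjusted over the list alone and 0 over all genes.

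Interferon-stimulated genes were higher in the same library. All 9 listed members of 44 were higher, including XAF1, a pro-apoptotic interferon target, IRF9, the DNA-binding part of the interferon-stimulated gene factor, and the transcription factor gene IRF1. XAF1 (ENSG00000132530, chromosome 17, 6755447 to 6775647) had 242 ± 274 normalized counts with GDF15 and 53.2 ± 23.8 without (SD, n = 3). IRF9 had 83.6 ± 42.7 and 36.4 ± 9.72, and IRF1 3322 ± 1677 and 2004 ± 215. STAT2, IRF7, PARP9, EPSTI1, GBP2 and BST2 were the other listed members, with groups that overlapped. GDF15 replicate 1 held the highest value of all 9, and the median log2 ratio of means was 0.83 with all libraries and 0.23 without it. The direction test (Fisher's exact) gave p = 0.0135 and adjusted p = 0.0629, and 0 members passed when adjusted over the list alone.

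Antigen presentation genes were listed as higher in 5 of 29 cases, with no overlap between groups for 4 of them. CD74, the invariant chain of MHC class II, had 178 ± 129 normalized counts with GDF15 and 59.5 ± 32.9 without (SD, n = 3), although GDF15 replicate 3 with 98.6 and untreated replicate 3 with 97.4 lay close together. CIITA, the class II transactivator gene, had 47.3 ± 8.68 and 25.6 ± 7.70, without overlap. Without GDF15 replicate 1 the log2 ratio of means of CD74 went from 1.58 to 0.80 and that of CIITA from 0.88 to 0.96. By limma on the log scale CD74 lost an unadjusted p under 0.05 without GDF15 replicate 1, untreated replicate 1 or untreated replicate 2. CIITA lost it without GDF15 replicate 2. TAPBP, the gene of tapasin, had 11246 ± 4607 and 7469 ± 723, and TAP1 and NLRC5 were 1.60-fold and 1.56-fold higher. By Fisher's exact test the list had p = 0.162 and adjusted p = 0.324, with 1 member past the threshold when adjusted over the list alone. The median log2 ratio of means of the list was 0.68 with all libraries and 0.30 without GDF15 replicate 1.

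**Figure D1:**
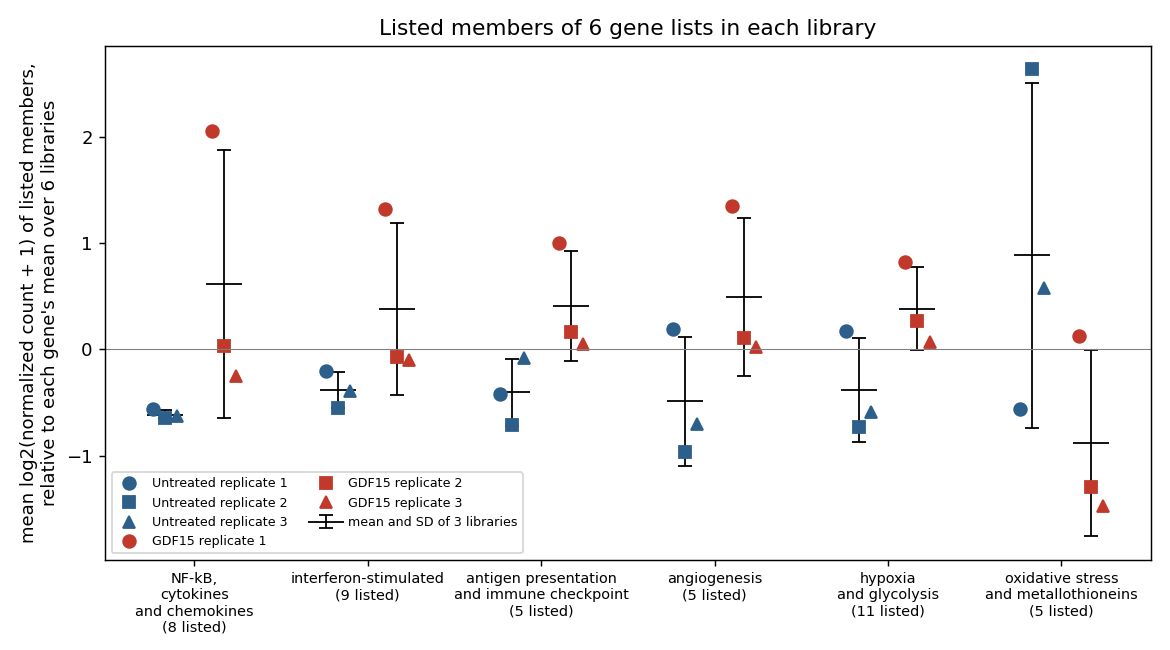
Mean log2(normalized count + 1) of the listed members of 6 gene lists in each library, relative to each gene's mean over the 6 libraries, with black lines for the mean and SD of 3 libraries. GDF15 replicate 1 (red circles) lies at 2.06 for the NF-kB list, where GDF15 replicates 2 and 3 lie at 0.03 and -0.25, and untreated replicate 2 (blue squares) lies at 2.63 for the oxidative stress and metallothionein list.

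Hypoxia and glycolysis genes formed the list with the most listed members. All 11 listed genes of 31 were higher. Among them were SLC16A3, the lactate exporter MCT4, the hexokinase gene HK2, the glucose transporter gene SLC2A1 and the mitophagy gene BNIP3. PFKFB3 and PFKFB4, whose products set the level of an activator of glycolysis, were listed too. SLC16A3 (ENSG00000141526, chromosome 17, 82228397 to 82261129) had 11855 ± 2537 normalized counts with GDF15 and 6167 ± 2525 without (SD, n = 3). By limma on the log scale SLC16A3 had an unadjusted p of 0.0174 with all libraries. This limma p was 0.0619 without untreated replicate 2 and 0.0567 without untreated replicate 3. PFKFB3 had 1748 ± 576 and 957 ± 548, and PFKFB4 1134 ± 388 and 691 ± 285, differences of 1.83-fold and 1.64-fold with overlapping groups. Groups did not overlap for 2 of the 11, SLC16A3 and the carbonic anhydrase gene CA12. Untreated replicate 1 held the highest untreated value of 10 of the 11 genes. For this list Fisher's exact test gave p = 0.00423 and adjusted p = 0.0592, the lowest of the 14 lists, and 1 member passed when adjusted over the list alone. With camera within the listed features the adjusted p was 0.0776 with the preset correlation, and adjusted p = 0.540 with an estimated correlation. The median log2 ratio of means was 0.72 with all libraries, 0.45 without GDF15 replicate 1 and 1.11 without untreated replicate 1.

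Angiogenesis genes were listed as higher in 5 of 41 cases. VEGFA, the main endothelial growth factor gene, had 927 ± 336 normalized counts with GDF15 and 542 ± 231 without (SD, n = 3). PDGFB, a growth factor gene whose product acts on stellate cells and pericytes, had 653 ± 142 and 413 ± 135 and was the only listed member whose groups did not overlap. By limma PDGFB had an unadjusted p of 0.0493 with all libraries. When a single library was left out, PDGFB kept a limma p under 0.05 only without untreated replicate 1. The VEGF receptor gene FLT1 had 172 ± 133 and 79.0 ± 26.1, and the secreted lipase inhibitor gene ANGPTL4 46.8 ± 36.2 and 14.2 ± 15.6. NRP2 was 1.74-fold higher with overlapping groups. Fisher's exact test gave p = 0.162 and adjusted p = 0.324, and 0 members passed when adjusted over the list alone. The median log2 ratio of means was 0.80 with all libraries and 0.44 without GDF15 replicate 1, which held the highest value of all 5.

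**Figure D2:**
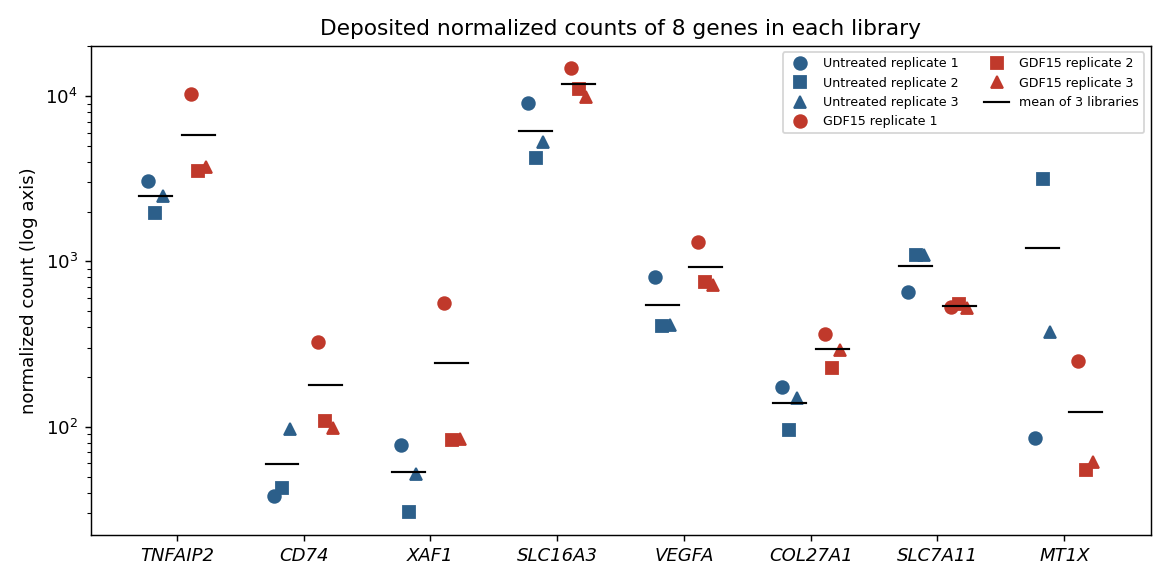
Deposited normalized counts (log axis) of 8 genes in each of the 6 libraries, red for GDF15 and blue for untreated, with black lines for the mean of 3 libraries. SLC7A11 lies between 524 and 551 in the 3 GDF15 libraries and between 648 and 1094 in the untreated ones, and MT1X reaches 3139 in untreated replicate 2.

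Metallothioneins had 4 of the 5 lowest fold changes. MT1X, MT1E, MT1M and MT1F, genes of small metal-binding proteins that lie together on chromosome 16, were 9.82-fold, 6.18-fold, 4.59-fold and 4.32-fold lower by the means. MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) had 122 ± 111 normalized counts with GDF15 and 1199.7 ± 1686 without (SD, n = 3). Its groups overlapped, with 3139 in untreated replicate 2, 374 in untreated replicate 3 and 85.0 in untreated replicate 1, below the 250.3 of GDF15 replicate 1. These paralogs are close in sequence, so their reads may be shared between them. With GCLM, a glutathione synthesis gene at 588 ± 21.6 against 943 ± 391, all 5 listed members of the 22 oxidative stress and metallothionein genes were lower. None of the 5 was free of overlap between the groups, and 4 of the 5 were higher in GDF15 replicate 1 than in untreated replicate 1. Untreated replicate 2 was highest for all 5, and the median log2 ratio of means was -2.20 with all libraries and -0.84 without it. Fisher's exact test gave p = 0.00931 and adjusted p = 0.0629, and 0 members passed when adjusted over the list alone. With camera the adjusted p was 0.0776 with the preset correlation, and adjusted p = 0.540 with an estimated correlation.

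Amino acid genes of the integrated stress response were also listed as lower. SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349), which imports cystine, had 536 ± 13.4 normalized counts with GDF15 and 943 ± 256 without (SD, n = 3), without overlap. Its unadjusted p of 0.000356 was the lowest among the lower features of the authors' deposited table. The serine synthesis gene PSAT1 had 1385 ± 97.51 and 2114 ± 721, and the asparagine synthetase gene ASNS 719 ± 16.4 and 1009.6 ± 326. DDIT4, an inhibitor of mTORC1 signalling, was higher at 1811 ± 526 against 972 ± 429. With 1 member higher and 3 lower of 32, Fisher's exact test gave p = 0.305 and adjusted p = 0.475, and 1 member passed when adjusted over the list alone. The median log2 ratio of means was -0.55 with all libraries and -0.24 without untreated replicate 2.

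Among genes of stellate activation and matrix turnover, PDGFRA, ENG, CTSK and PLAU were listed as higher. Of 29 stellate activation and contractile genes 2 were listed, both higher and without overlap. These were the growth factor receptor gene PDGFRA at 34.7 ± 13.96 against 15.3 ± 3.96 normalized counts and the TGF-beta co-receptor gene ENG at 3460 ± 564 against 2548 ± 556 (SD, n = 3). The log2 ratio of means of ENG was 0.44 with all libraries and 0.27 without untreated replicate 2, and limma gave it no unadjusted p under 0.05 in either case. Of 31 matrix proteases and inhibitors 2 were listed, the collagen-degrading cathepsin gene CTSK at 44.1 ± 8.49 against 23.6 ± 5.05 and the urokinase gene PLAU at 779 ± 116 against 574 ± 78.1. Of 29 TGF-beta and SMAD genes the stromal gene LRRC15 was listed, at 132 ± 27.3 against 79.6 ± 26.2, with a log2 ratio of means of 0.73, or 0.48 without untreated replicate 2. By limma PLAU had an unadjusted p of 0.0785 and LRRC15 of 0.0440 with all libraries. When a single library was left out, LRRC15 kept a limma p under 0.05 only without untreated replicate 1. By Fisher's exact test, two-sided, the adjusted p was 0.663 for each of the first 2 lists and 1.00 for the third, and 0 members of any passed when adjusted over the list alone. None of the 36 extracellular matrix genes was among the listed features, nor any of the 20 stellate quiescence genes. Outside the lists, and chosen after their values were seen, the collagen genes COL27A1 and COL7A1 had the lowest p-values of the authors' deposited table, 0.000125 and 0.000208. COL27A1 (ENSG00000196739, chromosome 9, 114155560 to 114312511) had 294 ± 69.2 and 139.8 ± 40.1, and COL7A1 (ENSG00000114270, chromosome 3, 48564073 to 48595267) 425 ± 128 and 205 ± 51.6, both without overlap.

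Immediate early genes and a p53 target were listed as higher and cell cycle genes as lower. EGR2, a growth-factor-induced transcription factor gene, had 35.3 ± 6.17 normalized counts with GDF15 and 14.8 ± 2.54 without (SD, n = 3), without overlap, while JUNB and the phosphatase gene DUSP5 were 1.60-fold and 1.48-fold higher with overlap. The 3 immediate early genes of 29 had a median log2 ratio of means of 0.68, or 0.40 without GDF15 replicate 1. Their direction had adjusted p = 0.475 by Fisher's exact test, with 1 member past the threshold when adjusted over the list alone. The mitotic kinase gene CDK1 had 2496 ± 161 and 3635 ± 1375, and the cyclin gene CCNA2 2822 ± 65.7 and 3475 ± 436, both lower without overlap. Of 45 cell cycle genes these 2 were listed, with adjusted p = 0.324 by Fisher's exact test, 0 past the threshold adjusted over the list alone, and a median log2 ratio of means of -0.42, or -0.19 without untreated replicate 2. The death receptor gene TNFRSF10B, the listed member of 23 p53 targets, was 1.56-fold higher with overlap, and its log2 ratio of means of 0.64 was 0.28 without GDF15 replicate 1 and 0.99 without untreated replicate 1. Its list had adjusted p = 1.00 by Fisher's exact test and 0 members adjusted over the list alone.

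The other lists had no listed member. They were histone genes (26), unfolded protein response (23), heat shock (16), cholesterol and lipid synthesis (28), ribosomal proteins (36), mitochondrially encoded genes (13) and nuclear genes of oxidative phosphorylation (36). The markers of other cells were likewise not among the listed features, with 18 hepatocyte, 13 cholangiocyte and epithelial, 13 endothelial, 15 leukocyte and macrophage and 10 melanocyte and melanoma genes. The levels of unlisted genes were not analysed here, so their absence from the list says nothing about their level.

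Several other genes met the rule of size and separation when it was applied to unadjusted p-values. Among the higher ones, the tight junction gene CLDN1 had 142 ± 142 normalized counts with GDF15 and 39.2 ± 5.99 without (SD, n = 3). The transcription factor gene CEBPD had 729 ± 561 and 279.7 ± 14.3, and RIPOR3 246 ± 126 and 106 ± 27.0. Without GDF15 replicate 1 their log2 ratios of means were 0.62, 0.54 and 0.71, against 1.86, 1.38 and 1.21 with all libraries. RFX8, BTBD19 and the meiotic cohesin gene REC8 were 2.17-fold, 2.08-fold and 2.09-fold higher. The log2 ratio of means of BTBD19 went from 1.05 to 0.68 without GDF15 replicate 3 and that of REC8 from 1.07 to 0.70 without GDF15 replicate 1. Among the lower ones, the chaperonin gene CCT6B was 2.86-fold lower at 12.95 ± 3.29 against 37.0 ± 13.5, and the monoamine oxidase gene MAOB 1.89-fold lower at 25.1 ± 6.48 against 47.6 ± 8.73. The NEDD8 protease gene SENP8 was 1.77-fold lower with little spread in either group, at 33.7 ± 2.88 against 59.4 ± 1.90. AKAP6, HENMT1 and RBP7 were 1.85-fold, 1.87-fold and 1.77-fold lower. Without untreated replicate 2 the log2 ratios of means of HENMT1 and RBP7 went from -0.90 to -0.52 and from -0.82 to -0.53, and both lost a limma p under 0.05. HENMT1 also lost it without GDF15 replicate 1, GDF15 replicate 2 or untreated replicate 3. RBP7 also lost it without GDF15 replicate 1 or GDF15 replicate 3. Most of the other lower genes named by the rule were long non-coding RNAs or pseudogenes of low level, such as BDNF-AS at 15.9 ± 0.546 against 29.7 ± 3.88, which lies antisense to BDNF.

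The higher and lower features differed in base composition. The median GC content of the longest annotated transcript was 56.8% over 274 higher and 42.0% over 177 lower features, a difference of 14.8 points. A permutation test of direction over features gave p = 0.0001, the smallest that 10000 permutations can give, although features are not independent replicates. Median transcript length was 3324 bases for higher and 2432 for lower features, with permutation p = 0.0001, again the smallest possible. Untreated replicate 2 held the highest value of 154 of the 179 lower features and the lowest value of 185 higher features. Whether these contrasts between higher and lower features rest on that library was not tested. The spike-in RNA on the list, added before library preparation and not made by the cells, had 16.98 ± 3.29 normalized counts in GDF15 libraries and 31.6 ± 6.37 in untreated libraries (SD, n = 3), without overlap.

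**Figure D3:**
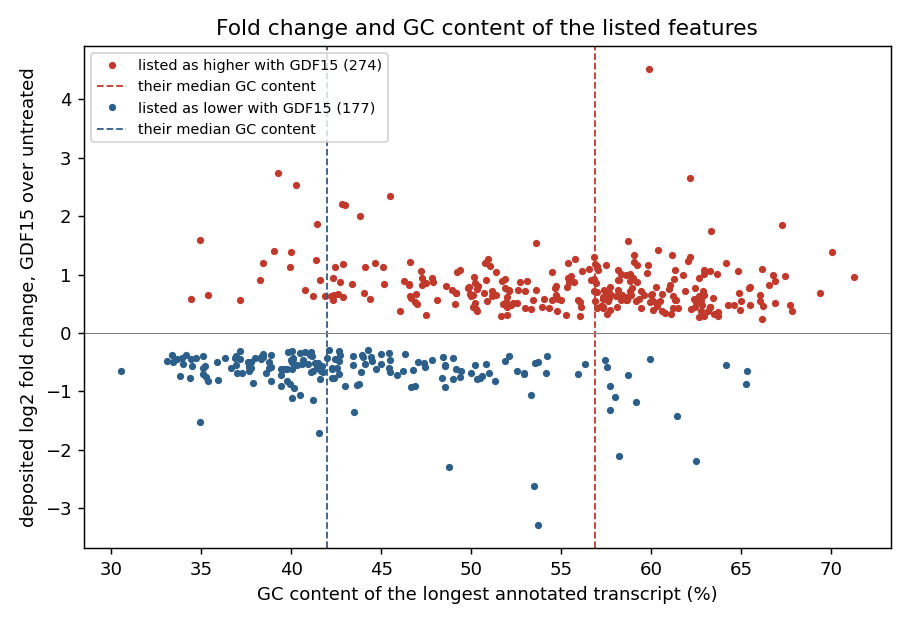
Deposited log2 fold change (GDF15 over untreated) of the listed features with an annotated transcript against the GC content of that transcript in percent, red for higher and blue for lower features. Dashed lines mark the medians, 56.8% for higher and 42.0% for lower features.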

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

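Leaving out GDF15 replicate 1 and untreated replicate 2 together, keeping list members with an unadjusted p under 0.01, and an estimated correlation with the replicate block were chosen after seeing the data. The counts of genes past an adjusted p of 0.05 stayed at 0 in both directions with a threshold of 0.01, with fold minimums and with a level minimum, since all share the deposited adjusted p of 0.911. Of the 274 features listed as higher, 63 had a fold of at least 2, 181 a fold of at least 1.5 and 176 a mean of at least 100 normalized counts. Of the 179 listed as lower, 17 had a fold of at least 2 and 90 a fold of at least 1.5. These settings keep fewer features by construction. By limma within the listed features, 104 were higher and 55 lower, within 1.5 times of these counts under other pseudocounts, and the minimum mean of 10 removed no feature. Leaving out each library in turn gave 55 (without untreated replicate 2) to 126 (without untreated replicate 1) higher and 24 (without GDF15 replicate 3) to 66 (without untreated replicate 1) lower features. Other counts beyond 1.5 times were 57 higher without untreated replicate 3 and 26 lower without GDF15 replicate 2. With both leading libraries left out, 66 were higher and 37 lower. These settings have fewer libraries, and the cause was not tested beyond that. The test of list direction had 0 lists past an adjusted p of 0.05. It had 1 among members with a fold of at least 2, 1 in a permutation test of the list median (oxidative stress and metallothioneins, adjusted p 0.0011), and 0 with camera under either correlation. Camera with each library left out gave 0 to 4 lists, with 4 without GDF15 replicate 3, 2 without untreated replicate 1 and 1 without GDF15 replicate 1, and the cause was not tested. GDF15 itself had a limma log2 change of 0.78, and 0.25 (without GDF15 replicate 1) to 1.39 (without GDF15 replicate 3) with each library left out, the last past an unadjusted threshold of 0.05. Of 57 other named genes, 36 had a limma p under 0.05, and 19 genes lost it without untreated replicate 2, 13 without untreated replicate 3, 9 without GDF15 replicate 2, 9 without GDF15 replicate 3, 8 without GDF15 replicate 1, 4 without untreated replicate 1, 15 with both leading libraries left out and 1 with a pseudocount of 0.1. Genes that gained it numbered 8 without untreated replicate 1, 3 without GDF15 replicate 3, 2 without GDF15 replicate 2, 2 without untreated replicate 3, 1 without GDF15 replicate 1, 0 without untreated replicate 2 and 2 with both left out. No limma direction of a named gene turned in these settings. The 15 highest and 15 lowest named genes were chosen without overlap between the groups, so their direction could not turn. Of the 274 higher features, 272 had a ratio of means above 1 without GDF15 replicate 1 and 270 with both leading libraries left out. All features were listed for their difference, so kept directions are no separate evidence.

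The replicate numbers were not treated as pairs, since the labels name no shared culture or day and not every correlation of same-numbered libraries' deviations from their group means was over 0.1 (0.11, 0.22 and -0.05). This leaves a pairing undecided. Fitted as a replicate block, the numbers gave 161 higher and 68 lower features by limma and 2 lists past the threshold with camera and the preset correlation, hypoxia and glycolysis (adjusted p 0.0428) and oxidative stress and metallothioneins (adjusted p 0.0461). With an estimated correlation and the block 0 lists passed, and both had adjusted p = 0.537. The GDF15 transcript stayed short of that threshold with the block, and 10 named genes gained a p under 0.05.

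DESeq2 in place of edgeR, other normalizations, count filters and scaling to spike-in totals were not run, since they need counts of all genes or all spike-ins. The unknown depth, the selection on p and 3 libraries per group limit every value.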

Other observations

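Genes outside the fixed lists, all chosen after their values were seen, add to the account. The complement protease genes C1S and C1R were 1.83-fold and 1.73-fold higher, at 857 ± 632 against 468 ± 33.7 and 3566 ± 2361 against 2067 ± 171 normalized counts (SD, n = 3), with overlap. Their log2 ratios of means were 0.07 and 0.09 without GDF15 replicate 1, down from 0.87 and 0.79, and C1R overlaps its listed neighbour C1RL on chromosome 12. The T cell costimulator gene TNFRSF9 was 4.02-fold higher with log2 ratios of 2.01 with all libraries and 0.28 without GDF15 replicate 1. The cytokine gene IL7 went from 1.199 to -0.12 in the same comparison. By contrast, the hypoxia-inducible host transcript of microRNA 210, MIR210HG, had 270.0 ± 22.6 against 134 ± 75.7 and a ratio of 1.05 without GDF15 replicate 1. NEAT1, a nuclear long non-coding RNA, had 6550.0 ± 1681 against 4092 ± 1154 and a ratio of 0.77 without that library. The clock genes PER1 and NR1D1 were 1.47-fold and 1.34-fold higher without overlap, at 850.0 ± 39.3 against 577 ± 184 and 553 ± 44.2 against 413 ± 52.7. How far NEAT1 and MIR210HG depend on libraries other than GDF15 replicate 1 is not given here. The same holds for PER1 and NR1D1 with any library left out.

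Among lower features, CYP1A1, the classic target of the aryl hydrocarbon receptor, had 168 ± 25.3 against 349 ± 145 normalized counts (SD, n = 3), and AHRR, the repressor of that receptor, 478 ± 9.52 against 655 ± 182. Their log2 ratios without untreated replicate 2 were -0.80 and -0.53, against deposited log2 fold changes of -1.06 and -0.46. Untreated replicate 2 therefore did not carry the difference of AHRR. How AHRR changes without the other untreated libraries is not given here. The kinetochore and spindle genes NDC80, SKA1, CENPH and TTK were 1.35-fold, 1.32-fold, 1.52-fold and 1.26-fold lower without overlap. Their log2 ratios were -0.18, -0.26, -0.21 and -0.22 without untreated replicate 2, against -0.44, -0.40, -0.61 and -0.33 with all libraries.

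All tests below were chosen after the results were seen. The 22 listed members of the NF-kB, interferon and antigen presentation lists exceeded the other GDF15 libraries in GDF15 replicate 1 by a median log2 of 1.44, against 0.35 for 252 other higher features and -0.07 for lower features. The members exceeded the lower features by 1.51 and the other higher features by 1.09, but neither value decides about a scaling error of that library or an equal response of the 3 GDF15 libraries. All features were listed for their difference between the groups, the pattern was seen before it was tested, and its genes vary together. RNA of leukocytes or endothelial cells stays open too, since 0 of 28 fixed markers were listed and unlisted levels were not analysed here, while CD34, SELPLG, FLT1, ENG and VCAM1, which such cells also express and which were chosen after their values were seen, had log2 fold changes of 0.49, 0.72, 1.13, 0.44 and 1.59 in the authors' deposited table. Without that library all 22 members were above 0, with a median log2 ratio of 0.25 against 0.89, but 9 of the 22 had both other GDF15 libraries above every untreated library, against 166 of 252 other higher features, and a response of the cells to GDF15 stays open as a hypothesis.

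Untreated replicate 2 was highest for most lower features. Its median log2 excess over the other untreated libraries was -0.368 in higher and 0.576 in lower features, which leaves a scaling error of it open, since listing by group difference favours such opposite signs. This excess fell with transcript length over 173 lower features, metallothioneins left out, with Spearman rho = -0.435 (95% bootstrap interval -0.56 to -0.29, across features, which are not independent replicates). It also fell with GC content, with rho = -0.231 (interval -0.37 to -0.08). A difference in RNA fragmentation or amplification of that library is a candidate explanation that these trends are consistent with, while a biological difference of that culture was not tested and stays open.

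The 11 hypoxia and glycolysis genes were all higher, with overlap for most. Of 10000 draws of 11 listed features matched on GC content, 1.08% were all higher, with a mean of 7.85 higher, which leaves GC content open, since the features were listed for their difference, the pattern was seen first and its genes vary together. For 10 of the 11 genes the same replicate number was highest in both groups, and 3 of 3 numbers deviated alike, with mean deviations of 0.43 in GDF15 replicate 1 and 0.56 in untreated replicate 1. These genes vary together, so they are not separate observations. GDF15 replicate 1 also held the highest value of 180 of the 274 higher features. Culture conditions shared by number, such as density or oxygen, may add to the spread of these genes, as a hypothesis, since the labels name no shared day. All 11 genes were higher in the GDF15 than in the untreated library for each of the 3 numbers. They were listed for their difference between the groups, which favours this count without fixing it, and they vary together. An effect of GDF15 therefore stays open.

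With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 159 features with a limma p under 0.05 and was the 1 split of 10 with as many, and the highest other gave 33. The features were listed for their difference in the real split, which alone raises its count.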
